A study of Mus musculus with 15 samples.

How the data were processed

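Poly(A) RNA of mouse perigonadal adipose tissue was measured by sequencing in 15 libraries, 1 per sample, from lean, obese and weight loss mice. The table the authors deposited holds expected counts per Entrez gene ID, not normalized, with 34.8% of the values not whole. The genome build was mm10 per the labels. The aligner, the counting tool and the annotation are not given in the sources used here, nor is the rule by which reads were shared out between genes. The table had 36172 lines for 35794 Entrez IDs, of which 74 stood on more than 1 line, with reads on at most 1 of them. Symbols came from the RefSeq gene table for 32919 IDs and from GENCODE M21 for 24, and 2851 IDs had none. Counts were rounded to whole numbers.

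As first laid out, all libraries that could be mapped to a label were to be used. Weight loss replicate 5 held 230 counts in all and was left out by a minimum total of 1000000 counts set after its total was seen. The design text of the series counts 4 weight loss samples. The other 14 libraries, 5 lean, 5 obese and 4 weight loss, held between 13924770 and 33807887 counts each.

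Genes were kept by edgeR's filterByExpr by group, which left 15208. Normalization factors were TMM, and 1 model with a coefficient for each of the 3 groups was fitted with edgeR 4.0.16 (estimateDisp, glmQLFit with package defaults, glmQLFTest) in R 4.3.3. All 3 pairwise comparisons were tested two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. CPM values are counts over the TMM-scaled library size, as edgeR computes them. Crispld2 also had an exact two-sided permutation test of log2 CPM. In total 37 gene lists were fixed before the data were examined, and 36 had at least 3 members past the filter. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Calls are also given adjusted over the list alone.

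Genes were named by a rule fixed before the data were examined. It took Crispld2, the 8 highest and 8 lowest log2 fold changes among called genes above a minimum average level, up to 4 called members of each list with the smallest p, 8 genes taken in every case, changed or not, and the most abundant member of each list of another cell type. Not every gene so taken is given below for every comparison. The correlations between comparisons were set beside 40 simulations of unchanged groups, and the overlaps beside independent lists of the same sizes and fits in which the shared group was split between both comparisons. The test was also checked on simulated data made from these libraries. Genes raised or lowered 2-fold were found in 53.7% of cases for obese against lean, 35.8% for weight loss against obese and 41.8% for weight loss against lean. For 1.5-fold the rates were 10.45%, 7.46% and 5.97% in the same order. This check changed 200 genes per comparison and drew each gene on its own, so rates in the real data can differ.

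Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, library size only, upper quartile), no filter or a CPM of at least 1 in at least 5 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, robust dispersion, only the groups compared, the replicate number as a block, an adjusted p of 0.01, and each library left out. Chosen after the data were seen were another edgeR setting (legacy=FALSE), inclusion of weight loss replicate 5, leaving out Lars2 and an Entrez ID without a symbol, whose shares of reads were uneven between libraries, the level of epididymal markers as a covariate, and leaving out the 4 libraries richest in them. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.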

Results

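Poly(A) RNA from perigonadal fat pads, the fat depot beside the gonads, was sequenced in C57BL/6 mice of 3 groups. Lean mice ate chow. Obese mice ate a 60% high-fat diet, which began at 8 weeks of age. Weight loss mice ate the same high-fat diet for 5 weeks and were then returned to chow for 1 week. All mice were 14 weeks old per the labels. The groups held 5 lean, 5 obese and 4 weight loss libraries, and the design text calls them independent samples. A further library, weight loss replicate 5, held 230 counts and entered no comparison. Totals of the 14 libraries used ran from 13924770 to 33807887 counts, and 15208 genes passed the filter on low counts. Expression levels are CPM, read counts scaled by library size and TMM factors, given as mean ± SD. Fold changes are log2 values ± standard error from edgeR's quasi-likelihood test. That test returns no standard error, so it was derived as the absolute log2 fold change over the square root of the test's F value.

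The title of the series names Crispld2, a gene for a secreted protein with a cysteine-rich domain, and its level was compared first. Crispld2 (Entrez ID 78892, protein-coding, chromosome 8, 119992438 to 120052794 on mm10) stood at 50.8 ± 3.6 CPM in lean fat (SD, n = 5), 48.2 ± 5.6 CPM in obese fat (SD, n = 5) and 69.8 ± 7.9 CPM after weight loss (SD, n = 4). Crispld2 rose 1.45-fold from obesity to weight loss, a log2 change of 0.54 ± 0.11 with a Benjamini-Hochberg adjusted p of 0.025. The lowest weight loss library, at 60.8 CPM, lay above the highest obese library, at 55.7 CPM. The exact two-sided permutation test of log2 CPM gave p = 0.00794 over 126 arrangements, the smallest value this design allows. Against lean fat the weight loss level was 1.37-fold, a log2 change of 0.46 ± 0.11. That difference had an adjusted p of 0.139 over all genes and p = 0.00794 in the exact permutation test of this gene alone. Between obese and lean fat Crispld2 differed by a log2 value of -0.08 ± 0.11, less than the spread between replicates (adjusted p = 0.714, exact permutation p = 0.365 over 252 arrangements). The adjusted p of the rise from obesity to weight loss lay near the threshold. It was above 0.05 when library totals alone set the scale (0.0563), when only both groups compared were fitted (0.0548) and with the epididymis level as a covariate (0.363) or without the 4 libraries richest in epididymal transcripts (0.388), alternatives chosen after the data were seen. It was also above 0.05 without weight loss replicate 1 (0.0681), weight loss replicate 3 (0.0912), obese replicate 3 (0.0761), obese replicate 4 (0.0591) or obese replicate 5 (0.0736).

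**Figure D1:**
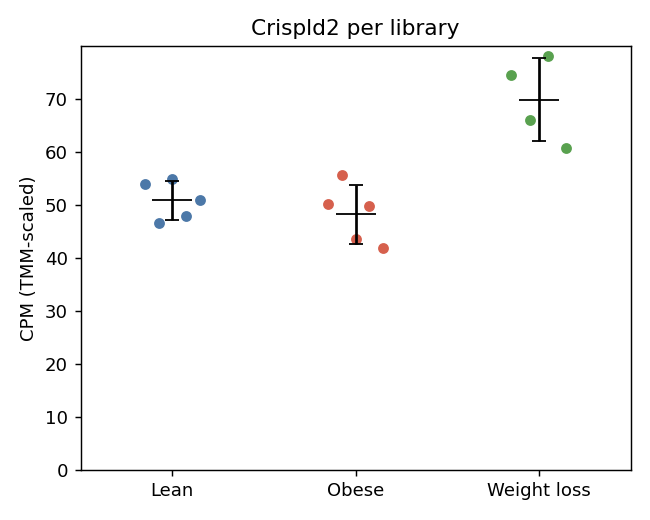
Crispld2 expression in CPM (vertical axis) in each lean, obese and weight loss library (points), with the group mean and SD (bars). The weight loss libraries lie between 60.8 and 78.1 CPM, above the highest obese library at 55.7 CPM.

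Obese against lean fat asked what high-fat feeding changed. The lists of cell cycle genes and of adipokines and fat expansion genes were higher in obese fat and circadian clock genes were lower, with the preset and with an estimated correlation. The summed level of the adipokine list was, however, lower in obese fat. Of the matrix genes 17 of 27 rose, and of general macrophage markers 13 of 17, with adjusted p = 0.211 and 0.363 with an estimated correlation. Mest, a marker of fat pad expansion, rose from 52.8 ± 26 to 523 ± 78 CPM, a log2 change of 3.30 ± 0.36. Lep, which encodes the satiety hormone leptin, rose from 601 to 1572 CPM (log2 1.39 ± 0.16). Sfrp5, a secreted inhibitor of Wnt signalling, rose from 23.4 ± 8.1 to 481 ± 132 CPM (log2 4.36 ± 0.51). In all, 1477 genes passed an adjusted p of 0.05, 891 higher and 586 lower in obese fat, and 502 of them changed over 2-fold.

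Of the 27 extracellular matrix genes, 17 rose and none fell, or 22 when adjusted over the list alone. Col6a2 and Col6a1, chains of type VI collagen, rose by log2 values of 1.46 ± 0.16 and 1.35 ± 0.17. Sparc, a collagen-binding matrix protein, rose from 1869 to 3516 CPM, and Timp1, an inhibitor of matrix metalloproteinases, rose by 1.97 ± 0.28. The list stood above other genes in camera with a preset correlation (adjusted p = 4.36e-15), and adjusted p = 0.211 with an estimated correlation. Of 17 general macrophage markers, 13 rose and none fell over all genes and over the list alone, among them C1qa (132 ± 39 to 291 ± 48 CPM), a complement component, and Cd68 (log2 1.41 ± 0.32). Adgre1, which encodes the F4/80 antigen, rose by 1.52 ± 0.43. Of 16 markers of lipid-associated macrophages 9 rose, or 13 adjusted over the list alone, including Lgals3 (log2 1.27 ± 0.20) and Itgax (log2 1.79 ± 0.39). Trem2, a lipid receptor of these cells, had a log2 value of 0.82 ± 0.31 and did not pass (adjusted p = 0.113). Both macrophage lists passed camera, at 8.06e-09 for the general and 1.17e-07 for the lipid-associated markers. With an estimated correlation their adjusted p values were 0.363 and 0.173. Of 21 inflammatory mediators 8 rose and none fell, and over the list alone 8 rose and 1 fell. The summed level of the list changed little, from 4698 ± 1259.8 CPM in lean to 4885 ± 1241.5 CPM in obese fat. The chemokine gene Ccl2 rose from 2.27 ± 1.0 to 13.4 ± 2.5 CPM, while Tnf stood at 1.14 and 1.22 CPM (adjusted p = 0.899). This list had a camera adjusted p of 0.000604, and adjusted p = 0.173 with an estimated correlation.

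Of 20 cell cycle genes 11 rose and none fell, or 14 adjusted over the list alone. Mki67, the gene of the Ki-67 proliferation antigen, rose from 10.04 ± 1.6 to 31.5 ± 7.3 CPM, and Top2a, a topoisomerase of dividing cells, from 5.78 ± 0.91 to 16.9 ± 2.8 CPM. Outside that list Cdkn1a, which encodes a cell cycle inhibitor, rose (log2 1.67 ± 0.19), from 27.2 to 86.4 CPM. The cell cycle list kept its call with an estimated correlation (adjusted p = 0.027), as did the list of adipokines and fat expansion genes (adjusted p = 0.0355). In the adipokine list 9 of 22 genes rose and 2 fell, or 9 and 3 adjusted over the list alone. Its summed level went the other way, from 18076 ± 3164 CPM in lean to 14671 ± 1625 CPM in obese fat. Angptl4, an inhibitor of lipoprotein lipase, rose by 1.05 ± 0.17. Crispld2 was 1 of the 22 members.

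Among 18 genes of de novo lipogenesis 6 fell and 2 rose, and over the list alone 7 fell and 2 rose. Their summed level was 21429 ± 4336 CPM in lean and 22965 ± 2176 CPM in obese fat. Acaca and Acacb, both acetyl-CoA carboxylases, fell by 1.40 and by 1.42 on the log2 scale, and Mlxipl, the transcription factor ChREBP, fell from 236 ± 65 to 107 ± 16 CPM. Fasn, fatty acid synthase, stood at 4442 CPM in lean and 2157 CPM in obese fat and did not pass (adjusted p = 0.0949). Of 18 adipocyte identity genes 6 fell and none rose over all genes, while over the list alone 6 fell and 1 rose. They included Cfd, the adipsin gene (log2 -1.45 ± 0.26), Slc2a4, the insulin-regulated glucose transporter (340 ± 54 to 204 ± 19 CPM), and the adipogenic factor Cebpa (log2 -0.57 ± 0.11). Adipoq, the adiponectin gene, did not pass (log2 0.25 ± 0.12, adjusted p = 0.227). Camera called both lists lower, with adjusted p = 0.00358 for lipogenesis and 0.0179 for identity, and adjusted p = 0.509 and 0.569 with an estimated correlation. With the epididymis level as a covariate the identity list no longer passed. Of 13 triglyceride synthesis genes 4 fell and 1 rose, or 6 and 3 adjusted over the list alone, and camera did not call the list (adjusted p = 0.128). Gpat3 (log2 -1.17 ± 0.12) and Slc27a1 fell, and Mogat2, a monoacylglycerol acyltransferase, rose from 2.22 to 17.7 CPM. Npr3, the clearance receptor of natriuretic peptides, rose by 1.44 ± 0.21.

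Circadian clock genes fell as a group, with 8 of 14 lower and none higher in obese fat, or 10 lower adjusted over the list alone. Ciart fell from 23.0 ± 5.1 to 6.63 ± 1.4 CPM, Per3 from 97.0 ± 3.5 to 50.5 ± 9.0 CPM and Dbp from 344 ± 57 to 151 ± 49.5 CPM. Tef fell by 0.69 on the log2 scale. The list was lower in camera with the preset (adjusted p = 2.01e-06) and adjusted p = 0.00868 with an estimated correlation.

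Outside the lists, the choline transporter gene Slc5a7 rose from 0.0997 ± 0.16 to 8.76 ± 2.1 CPM and Fgf13 from 2.61 ± 0.60 to 31.2 ± 3.6 CPM. Cyp2f2, a cytochrome P450 gene, fell from 123 ± 68 to 4.52 ± 2.0 CPM, and Hpca fell by 3.75 on the log2 scale. Markers of the epididymis, the tissue that the fat pad adjoins in male mice, differed widely between libraries. Their summed level was 8208, 6480 and 3048 CPM in obese replicates 2, 5 and 4 and 3322 CPM in lean replicate 1, against 546 CPM or less in each of the other 10 libraries. The gene with the greatest rise, Lcn5 (log2 8.66 ± 2.25), was such a marker and reached 1162 CPM in obese replicate 4 against 4.30 CPM or less in each of the others. The count of called genes was 1010 with the epididymis level as a covariate and 125 without the 4 libraries richest in these transcripts, which left 2 obese libraries. Both alternatives were chosen after the data were seen, and the 4 libraries were picked by summed level. By the mean log2 CPM of the markers, obese replicate 3 (4.61), which was kept, stood above obese replicate 4 (2.71). DESeq2's Wald test called 2260 genes. Leaving out obese replicate 2, obese replicate 3, obese replicate 4 or lean replicate 5 gave 849, 887, 929 and 903 genes.

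**Figure D2:**
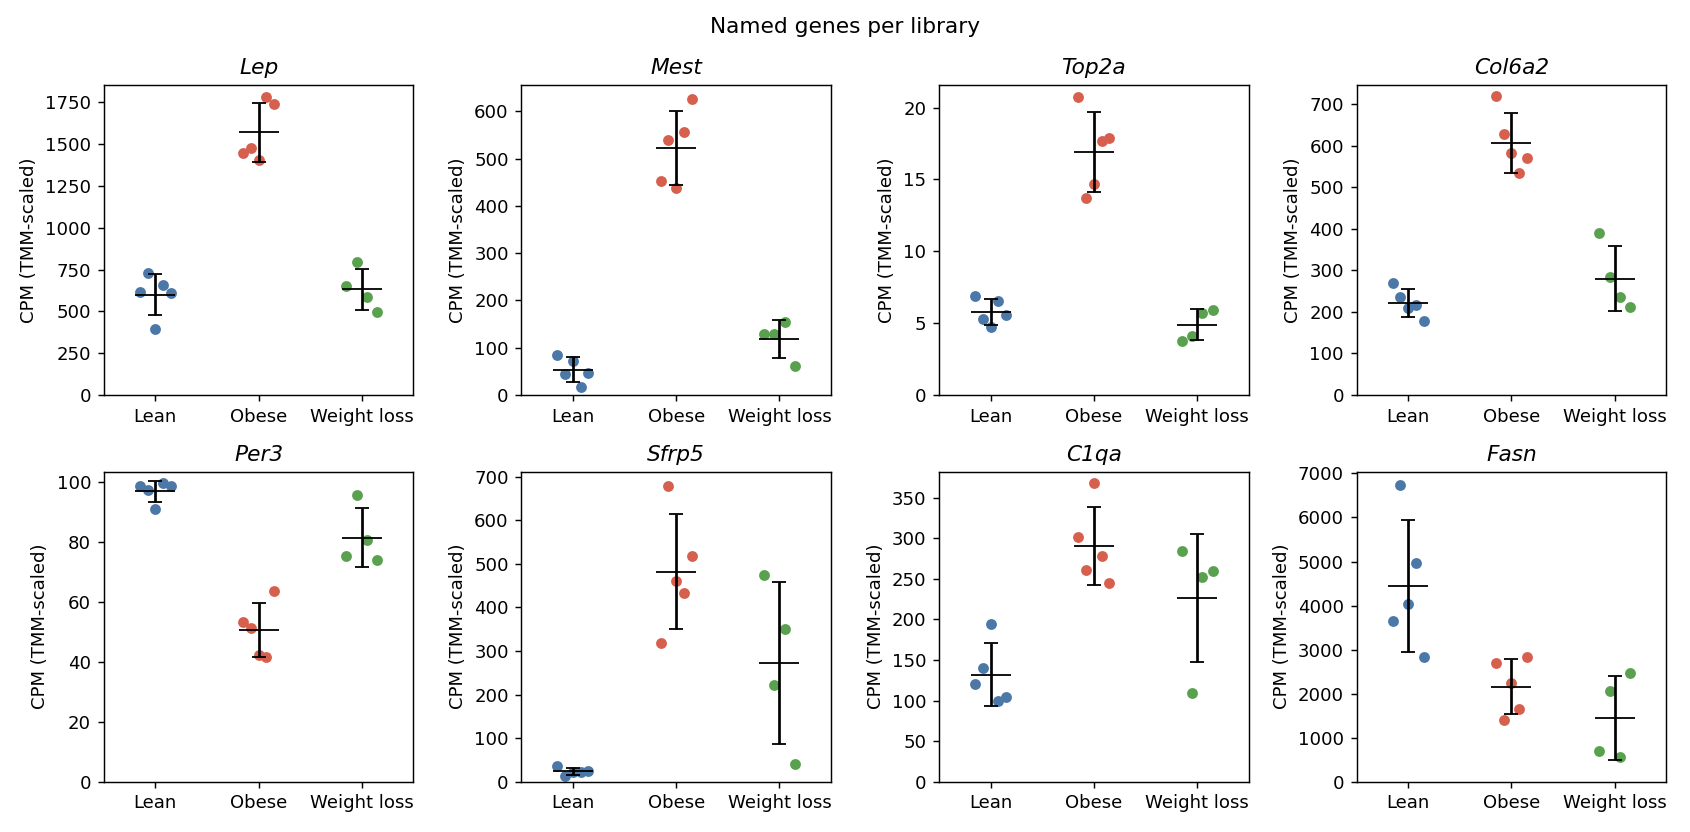
Expression in CPM (vertical axes) of 8 genes in each lean, obese and weight loss library (points), with the group mean and SD (bars). Lep, Mest, Top2a and Col6a2 were higher in obese than in lean fat, and the weight loss means of Lep (631 CPM) and Top2a (4.88 CPM) lay near the lean means of 601 and 5.78 CPM.

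Weight loss against obese fat asked what 1 week back on chow changed. The cell cycle list was lower and the circadian clock list higher after weight loss, with the preset and with an estimated correlation, and no macrophage marker passed the test over all genes. Lep fell from 1572 to 631 CPM, a log2 change of -1.32 ± 0.18. Mest fell from 523 ± 78 to 118 ± 40 CPM and Mogat2 from 17.7 ± 4.8 to 1.89 ± 0.81 CPM. The test called 246 genes, 112 higher and 134 lower after weight loss.

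Of the 20 cell cycle genes 6 fell and none rose, or 15 adjusted over the list alone. Top2a fell from 16.9 ± 2.8 to 4.88 ± 1.1 CPM (log2 -1.79 ± 0.21), Mki67 by 1.52 and Birc5, the survivin gene, by 1.37 on the log2 scale. Cdkn1a fell from 86.4 to 28.6 CPM. The list had an adjusted p of 1.34e-15 in camera, and adjusted p = 0.00424 with an estimated correlation. Of the 14 clock genes 6 rose and none fell, or 8 adjusted over the list alone (camera adjusted p = 1.33e-08, and adjusted p = 0.00204 with an estimated correlation). They included Per3 (50.5 ± 9.0 to 81.4 ± 9.9 CPM), Hlf (log2 0.89 ± 0.17), Per2 (log2 0.67 ± 0.13) and Ciart (log2 1.29 ± 0.26).

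Among 27 matrix genes 5 fell and none rose, while over the list alone 9 fell and 1 rose. Col6a2 fell by 1.12, Sparc by 0.71 and Col4a2, a basement membrane collagen, by 0.83 on the log2 scale. Of 19 cholesterol synthesis genes 3 fell, or 12 adjusted over the list alone with 1 higher. Insig1, a sterol-regulated membrane protein, fell by 0.66 on the log2 scale. Camera called matrix (adjusted p = 1.45e-05) and cholesterol synthesis (adjusted p = 1.15e-09) lower, and adjusted p = 0.72 and 0.106 with an estimated correlation. Of the mediators of inflammation Orm1, an acute-phase protein, fell from 362 ± 90.1 to 86.1 ± 44 CPM and the chemokine Ccl8 by 2.15 on the log2 scale. The inflammatory list had 2 of 21 genes lower, or 3 adjusted over the list alone (adjusted p = 0.00647, and adjusted p = 0.239 with an estimated correlation). The neutrophil gene S100a8 fell from 4.39 ± 0.96 to 0.523 ± 0.20 CPM. The neutrophil list did not move with it, with 1 call among 8 genes, 4 of the 8 positive and a camera adjusted p of 0.625. General macrophage markers had 0 calls among 17 genes, over all genes and over the list alone, with a camera adjusted p of 0.0426 for lower levels, and adjusted p = 0.868 with an estimated correlation. C1qa had a log2 value of -0.36 ± 0.25 and Adgre1 of -0.10 ± 0.45. Trem2 stood at 18.0 CPM in obese fat and 24.8 CPM after weight loss (adjusted p = 0.582).

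Of 13 triglyceride synthesis genes 3 rose and 1 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.781). Of 18 de novo lipogenesis genes 1 fell, while over the list alone 3 rose and 3 fell (adjusted p = 0.186), and of 15 lipolysis genes 1 fell over all genes and over the list alone (adjusted p = 0.311). Scd2, a stearoyl-CoA desaturase, fell from 510 ± 82 to 144 ± 52 CPM, and Npr3 fell by 1.06. Gpat3 rose by 0.82 ± 0.13, Lpin1, a phosphatidate phosphatase, by 0.58 ± 0.10 and Slc27a1, a fatty acid transporter, by 0.94 ± 0.20. Fasn had a log2 value of -0.57 ± 0.40 (adjusted p = 0.579). Outside the lists Nat8l, which makes N-acetylaspartate, rose from 56.6 ± 13 to 177 ± 24 CPM, near the lean level of 179.5 ± 55 CPM. Lrrc4 rose by 1.87 ± 0.24 and the carboxylesterase gene Ces1f by 1.42 ± 0.22. Epididymal markers summed to between 0.784 and 61.5 CPM in the weight loss libraries. With that level as a covariate 34 genes were called, 7 higher and 27 lower and all among the 246, and without the 4 libraries richest in it 20, of which 2 were higher and 18 lower. DESeq2's Wald test called 691 genes and limma-voom with sample quality weights 533. Leaving out 1 library gave 141 genes without weight loss replicate 3, 143 without obese replicate 3, 141 without obese replicate 4 and 152 without obese replicate 5.

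Weight loss against lean fat asked what remained different after the diet was switched back. Only 5 genes passed, all higher after weight loss. Of the 15208 genes tested, 1739 had an unadjusted p under 0.05 in edgeR's test, which a share of 0.05 of unchanged genes would pass by chance. Sfrp5 was higher by 3.54 ± 0.50 and Thbs2, a matrix glycoprotein, by 3.43 ± 0.47 on the log2 scale. Srpx2 was higher by 1.12 ± 0.16, Fbxo21, an F-box protein, by 0.86 ± 0.10 and Amy1 by 0.64 ± 0.09. Amy1 belongs to a family of amylase genes, and how reads were shared between related genes is not given. Lep stood at 631 CPM after weight loss and 601 CPM in lean fat (log2 0.07 ± 0.17, adjusted p = 0.906).

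No macrophage marker passed over all genes, though 12 of 17 general and 11 of 16 lipid-associated markers were higher when adjusted over the list alone. Camera gave the general markers an adjusted p of 8.41e-09, and adjusted p = 0.35 with an estimated correlation. Trem2 had a log2 value of 1.28 ± 0.33 (adjusted p = 0.151) and Ccl2 of 1.63 ± 0.45 (adjusted p = 0.178). Camera placed the lipid-associated markers above other genes (adjusted p = 2.83e-12, and adjusted p = 0.136 with an estimated correlation). Matrix genes had 1 call over all genes and 13 over the list alone, and camera gave an adjusted p of 2.36e-10, and adjusted p = 0.35 with an estimated correlation. Progenitor markers had 0 calls over all genes and 8 over the list alone, among them Ly6a at 214 ± 15 CPM in lean fat and 333 ± 72 CPM after weight loss (list adjusted p = 1.47e-05, and adjusted p = 0.35 with an estimated correlation). De novo lipogenesis genes had 0 calls over all genes, and over the list alone 13 of 18 were lower and 1 higher. Their summed level did not fall, at 21429 ± 4336 CPM in lean fat and 21449 ± 3479 CPM after weight loss. Fasn stood at 4442 CPM in lean fat and 1450.0 CPM after weight loss (log2 -1.62 ± 0.41, adjusted p = 0.151). Camera placed this list below other genes (adjusted p = 2.36e-10, and adjusted p = 0.144 with an estimated correlation). The count of 5 was 0 when only both groups compared were fitted, with the epididymis level as a covariate, and without the 4 libraries richest in epididymal transcripts. It was 130 without weight loss replicate 4, and 0 without weight loss replicate 3 or lean replicate 4. Without weight loss replicates 1 and 2 it was 1 and 11, without lean replicates 2, 3 and 5 it was 2, 16 and 2, and without obese replicate 3 or 5 it was 3. DESeq2's Wald test called 261 genes, limma-voom 1, and limma-voom with sample quality weights 3.

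Of the 1477 genes that differed between obese and lean fat, 203 changed back with weight loss, 116 that were higher and 87 that were lower in obese fat. Lep, Mest, Top2a, Col6a2 and Per3 were among them. The count was 496 with DESeq2, 399 with limma-voom with sample quality weights, 34 with the epididymis level as a covariate and 17 without the 4 libraries richest in epididymal transcripts. It was 129, 135, 122, 122 and 135 without weight loss replicates 3 and 4 or obese replicates 3, 4 and 5. Opposite signs held for 95.3% of the 1477 genes. Both comparisons share the obese libraries, so 40 simulations of unchanged groups were run, which gave a mean correlation across genes of -0.456 against -0.595 observed. The simulations called at most 1 gene in a comparison and so give no value for the overlaps. They drew each gene on its own and hold no genes that vary together, as the epididymal markers do. A larger correlation or covariance than simulated, here and below, therefore cannot be read as an effect of weight loss alone. The covariance was -0.305 observed and -0.0891 in the simulations, and independent lists of these sizes would share 12.2 genes. With the obese libraries split so that the comparisons shared none, the overlap was 30 to 84 genes over 20 arrangements and the sign was opposite for a median of 94.4% of the called genes. The correlation was then -0.292 on average (-0.506 to 0.107) and the covariance -0.158 (-0.261 to 0.0665). In 4 genes, Amy1, Thbs2, Sfrp5 and Srpx2, obesity and weight loss both differed from lean fat in the same direction. The count was 195 with DESeq2, 2 with limma-voom with sample quality weights, and 0 with limma-voom, with only the groups compared, with the epididymis covariate and without the 4 libraries. It was 109, 14 and 8 without weight loss replicate 4, lean replicate 3 and weight loss replicate 2, 2 without obese replicate 2 or 5, 1 without lean replicate 2 or obese replicate 3, and 0 without weight loss replicate 1 or 3 or lean replicate 4 or 5. Independent lists would share 0.293 genes, and splits of the lean libraries gave 0 to 7 genes. Across the 1477 genes the slope of weight loss minus lean on obese minus lean was 0.443, and with the lean libraries split it had a median of 0.296 (-0.0906 to 0.474), while 91.3% of the genes shared their sign against a median of 79.6% in the splits. The correlation of these 2 comparisons was 0.202 against a simulated 0.478, and the covariance was 0.0849 against 0.0944. In the splits they were -0.0896 (-0.475 to 0.284) and -0.0967 (-0.425 to 0.109) on average. Only Fbxo21 differed in the same direction from obese and from lean fat, and Crispld2 did not because its adjusted p against lean fat was 0.139. This count was 31 with DESeq2, 6 without weight loss replicate 4, 2 without lean replicate 5, and 0 without weight loss replicate 3 or lean replicate 4, with only the groups compared, with the epididymis covariate and without the 4 libraries. Here independent lists would share 0.0368 genes and splits of the weight loss libraries gave 0 to 3 genes, with a correlation of 0.667 against a simulated 0.563 and a covariance of 0.368 against 0.118. In the splits the correlation was 0.429 (0.261 to 0.511) and the covariance 0.322 (0.230 to 0.357) on average. The epididymal markers had a median log2 value of -10.2 in weight loss against obese and -7.19 in weight loss against lean. Splits of the weight loss libraries can keep such a shared difference.

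**Figure D3:**
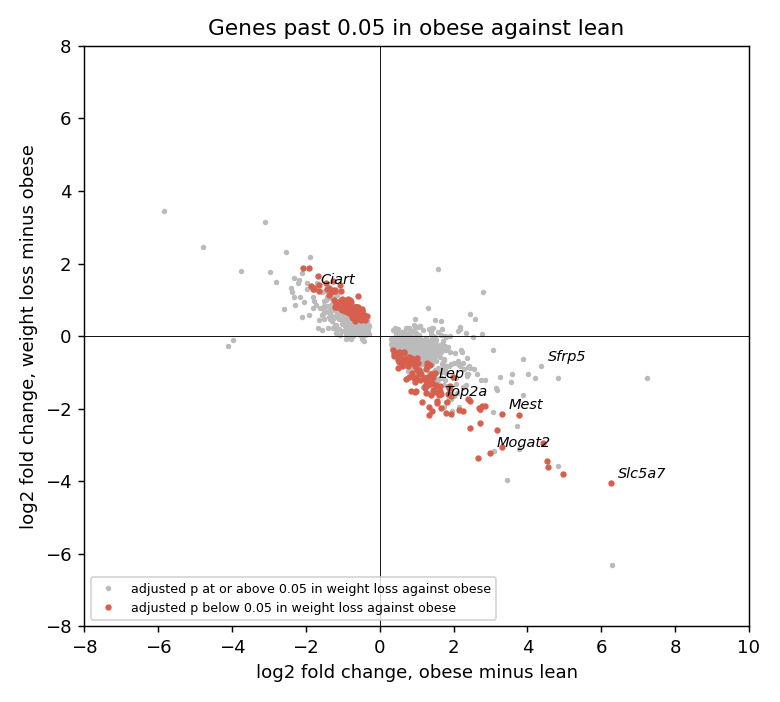
Log2 fold change of obese minus lean (horizontal axis) against weight loss minus obese (vertical axis) for the genes called in obese against lean fat. Each point is 1 of the 1477 genes, red where weight loss against obese also passed an adjusted p of 0.05, and 1 gene lies outside the plotted range. Of the genes, 95.3% had opposite signs.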

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

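The tests of other splits of the libraries and those of time of day, adipocyte share and progenitor share were chosen after the results were seen, as were the fits with an epididymis covariate, without the 4 libraries richest in epididymal transcripts and without an Entrez ID that has no symbol and Lars2.

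The number of genes that differed between obese and lean fat, 1477, stood beside epididymal transcripts whose summed level was highest in 3 obese libraries and 1 lean library. By the mean log2 CPM of the markers, obese replicate 3 (4.61, with a sum of 441 CPM) stood above obese replicate 4 (2.71). With the epididymis level as a covariate the median called gene kept 100.1% of its log2 fold change (quartiles 91.5% and 109%). Of the 1477 genes, 911 were still called. These values argue against epididymal RNA, as that level measures it, as the whole cause. Without the 4 libraries with the highest sums, which left 2 obese libraries, 124 were still called and 99.9% kept their sign. That refit cannot decide the question, because the genes were chosen on data that include the libraries it kept. It also kept obese replicate 3. Without Lars2 and an Entrez ID that has no symbol, which held up to 1.43% and 7.88% of the reads of a library used, 1516 genes were called, which argues against these 2 as the cause. Chance was argued against for this comparison, since the real split, 1 of 100, gave 1477 genes and the highest other 55. The same held for weight loss against obese, where the real split, 1 of 100, gave 246 and the highest other 0. Splits do not separate the groups from epididymal RNA. The split with 55 genes parted libraries with a mean log2 CPM of epididymal markers up to 0.046 from those at 2.71 or more. In weight loss against obese, 34 of the 246 calls were left with the epididymis covariate. For weight loss against lean chance was left open, since 5 of 100 splits gave at least the 5 genes found. The highest, 245 genes, set lean replicates 1, 4 and 5 and weight loss replicate 4 against the rest, which points to a structure of the samples. Those libraries had the highest values of both groups on principal component 1 of the 500 most variable genes (47.8% of the variance). Epididymal genes such as Gpx5 and Crisp1 led that component. Their epididymal sums were not all the highest, with 7.59 CPM in lean replicate 5 against 20.4 CPM in lean replicate 2.

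Clock genes with 8 calls, among them Ciart, Per3, Dbp and Tef, were lower in obese than in lean fat, with a median log2 fold change of -0.83 and an upper quartile of -0.70. With the epididymis covariate their median kept 99.6% of its size, and 6 of the 8 were still called. A lower share of adipocytes as the whole of this fall was argued against by the adipocyte identity list, whose median was -0.10 (quartiles -0.54 and 0.08). A part of it is not argued against, because 6 of the 18 identity genes fell and none rose. Camera called that list lower (adjusted p = 0.0179, and adjusted p = 0.569 with an estimated correlation). Its summed level was 50806 ± 5881 CPM in lean and 42483 ± 4406 CPM in obese fat. Collection at different times of day cannot be told apart from the diet, because Arntl, Npas2, Clock and Cry1, which peak in the opposite phase, had a median of 0.23 with upper 95% limits as high as 1.65, and no time of collection was recorded in the labels. An effect of the diet on the clock, untested here, stays open beside it.

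Crispld2 was higher after weight loss than in obese fat by a log2 value of 0.54 ± 0.11. With the epididymis covariate it was 0.50 ± 0.16 (95% interval 0.16 to 0.83), and the call ended (adjusted p = 0.363, with 0.00066 to 0.388 over all alternatives) with little change in the fold and a wider standard error. Leaving out 1 library gave 0.48 at the lowest, without weight loss replicate 3, where the call also ended (adjusted p = 0.0912). A larger share of adipocyte progenitors was argued against by their list, with a median of -0.0333 (quartiles -0.15 and 0.18). The rise may be a response to weight loss, a hypothesis found and tested on the same data. The return to chow itself cannot be told apart from weight loss in this design. Differences between mice and collection are also left open.

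Single libraries stood far from the others of their group in 11 of 210 groups of values examined, and chance gives about 1 in 20. C1qa was 109.6 CPM in weight loss replicate 2 against 252 to 285 CPM in the other weight loss libraries. Cdkn1a was 62.2 CPM in obese replicate 2 against 87.4 to 97.5 CPM. Cebpa was 422 CPM in lean replicate 1 against 539.7 to 592 CPM. Per3 was 90.8 CPM in lean replicate 3 against 97.3 to 99.5 CPM. Col4a2 was 1184 CPM in obese replicate 1 against 958 to 980.4 CPM. Insig1 was 74.6 CPM in weight loss replicate 1 against 97.7 to 102.5 CPM.

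Srpx2 was 23.7 CPM in lean replicate 4 against 18.4 to 19.5 CPM in the other lean libraries. Lcn5 was 0.107 CPM in weight loss replicate 4 and 0 in the other weight loss libraries. Ucp1, the uncoupling protein of brown fat, was 13.7 CPM in weight loss replicate 3 against 0 to 0.641 CPM. An Entrez ID without a symbol held 7.88% of the reads of lean replicate 2 against 2.14% to 2.64%, and Lars2 held 1.43% against 0.405% to 0.593%. Weight loss replicate 5, used in no comparison, held 230 counts.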

How the results depend on the processing

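The fits with legacy=FALSE, with weight loss replicate 5, with an epididymis covariate and without the 4 libraries richest in epididymal transcripts were chosen after the results were seen. Counts are given in the order obese against lean, weight loss against obese, weight loss against lean, changed back, still changed and set apart (1477, 246, 5, 203, 4 and 1), and a count not given was within 1.5 times. The cause was not tested unless stated. Scaling by DESeq2 size factors or upper quartile moved no count that far, nor did library size alone, under which Crispld2 in weight loss against obese was 0.55 (adjusted p = 0.0563). DESeq2 gave 2260, 691, 261, 496, 195 and 31, with Crispld2 in weight loss against lean at 0.44 (adjusted p = 0.0193). Limma-voom gave 1 for weight loss against lean and 0 still changed. Sample quality weights gave 533 for weight loss against obese, 3 for weight loss against lean, 399 changed back and 2 still changed. The filter at a CPM of 1 and legacy=FALSE each gave 2 set apart. With only the groups compared, weight loss against lean, still changed and set apart were 0, and Crispld2 was 0.53 (adjusted p = 0.0548). The replicate block gave 2, 2 and 0 for these, with 0 of the 5 genes of weight loss against lean among its 2, and Crispld2 at 0.51 (adjusted p = 0.0713). Replicate numbers did not pair the mice: 3 of 14 libraries correlated best with their own number. With weight loss replicate 5 included, 10 genes differed in weight loss against lean and 9 were still changed, and the adipocyte identity list turned lower in weight loss against obese (adjusted p = 0.823). The covariate gave 34, 0, 34, 0 and 0 from weight loss against obese on, with Crispld2 at 0.50 (adjusted p = 0.363). Without the 4 libraries, which left 2 obese libraries, counts were 125, 20, 0, 17, 0 and 0, Crispld2 was 0.58 (adjusted p = 0.388) and Lcn5 in obese against lean was -0.76. At an adjusted p of 0.01, a stricter threshold by construction, counts were 463, 84, 0, 73, 0 and 0 and Crispld2, at 0.54, did not pass.

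With each library left out, obese against lean gave 849 (without obese replicate 2) to 1673 genes (lean 3), weight loss against obese 141 (weight loss 3) to 265 (lean 1) and weight loss against lean 0 (weight loss 3) to 130 (weight loss 4). Changed back ran from 122 (obese 3) to 228 (lean 1), still changed from 0 (weight loss 1) to 109 (weight loss 4) and set apart from 0 (weight loss 3) to 6 (weight loss 4). Crispld2 ran from -0.13 to -0.05 in obese against lean, from 0.48 to 0.59 in weight loss against obese (adjusted p from 0.0202 to 0.0912) and from 0.40 to 0.49 in weight loss against lean (adjusted p from 0.0596 to 0.518).

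Fry, which tests whether the genes of a list move one way and does not compare the list with other genes, left 81 list results on the same side of the threshold, ended 25 calls and added 2. In obese against lean it ended those of adipocyte identity and de novo lipogenesis (both adjusted p = 0.0951), interferon response (0.137), epididymis (0.152) and oxidative phosphorylation (0.255), and added neutrophil (0.0123). In weight loss against obese it ended inflammatory (0.0521), epididymis (0.0857), matrix (0.287), antigen presentation (0.325), adipocyte identity (0.37) and general macrophage (0.601). In weight loss against lean it ended matrix (0.106), general macrophage (0.111), tissue-resident macrophage (0.196), progenitor (0.0669), cholesterol synthesis (0.0846), oxidative phosphorylation (0.376) and 8 others, and added hypoxia (0.0335).

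Of the list results, 78 kept their direction and side of the threshold with weight loss replicate 5 included, where 19 calls ended, 10 were added and 1 list turned, and the clock list lost its calls in obese against lean (adjusted p = 0.108) and in weight loss against obese (0.227). The covariate ended 8 list calls and added 3, lower tissue-resident macrophage, interferon response and progenitor lists in weight loss against obese. Without the 4 libraries 6 ended and 8 were added. With each library left out 1 to 10 list calls ended, 1 without lean replicate 5 and 10 without weight loss replicate 4, and up to 6 were added, without weight loss replicate 2.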

Other observations

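The lists below were fixed before the data were examined, and no further test was chosen after the results were seen. In obese against lean fat, tissue-resident macrophage markers had 4 of 13 genes higher, while over the list alone 9 were higher and 1 lower (camera adjusted p = 2.35e-05, and adjusted p = 0.502 with an estimated correlation). Adipocyte progenitor markers had 6 of 14 genes higher over all genes and over the list alone, with Ly6a rising from 214 ± 15 to 323 ± 27 CPM (adjusted p = 0.000655, and adjusted p = 0.502 with an estimated correlation). Antigen presentation genes had 3 of 11 higher, or 7 adjusted over the list alone (adjusted p = 0.00824, and adjusted p = 0.509 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, rose from 0.433 to 4.39 CPM, 1 of 2 genes called among 8 neutrophil markers. Interferon response genes had 1 of 15 higher and 0 over the list alone, and immediate early genes 2 of 12 over all genes and over the list alone. Both had a camera adjusted p of 0.0254, and adjusted p = 0.569 and 0.502 with an estimated correlation.

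Oxidative phosphorylation genes had 1 of 19 lower in obese than in lean fat, over all genes and over the list alone (camera adjusted p = 0.00967, and adjusted p = 0.569 with an estimated correlation). Against lean fat the same list was lower after weight loss with 0 calls over all genes and over the list alone (adjusted p = 0.000433, and adjusted p = 0.498 with an estimated correlation). Cholesterol synthesis genes were lower after weight loss than in lean fat, with 0 of 19 calls and 1 lower over the list alone (adjusted p = 6.3e-06, and adjusted p = 0.324 with an estimated correlation). Adipocyte identity genes had 0 of 18 calls in weight loss against obese fat and 3 higher over the list alone (adjusted p = 0.0313, and adjusted p = 0.792 with an estimated correlation). The 10 epididymal markers had 0 calls in that comparison and 9 lower over the list alone (adjusted p = 7.8e-07, and adjusted p = 0.28 with an estimated correlation).

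Other lists passed camera with the preset correlation and not with an estimated one. In weight loss against obese fat, antigen presentation genes were lower (adjusted p = 0.0268, and adjusted p = 0.72 with an estimated correlation), as were adipokine and fat expansion genes (0.0299, and adjusted p = 0.215 with an estimated correlation), while hypoxia genes were higher (0.0467, and adjusted p = 0.215 with an estimated correlation). In weight loss against lean fat, tissue-resident macrophage markers were higher (1.48e-05, and adjusted p = 0.403 with an estimated correlation), as were adipokine and fat expansion genes (0.00152, and adjusted p = 0.136 with an estimated correlation). Mesothelial markers (0.00416), mast cell markers (0.023) and immediate early genes (0.0418) were also higher there, each with adjusted p = 0.403 with an estimated correlation. So were endoplasmic reticulum stress genes (0.0183, and adjusted p = 0.35 with an estimated correlation) and interferon response genes (0.0296, and adjusted p = 0.569 with an estimated correlation). Triglyceride synthesis (0.0234), smooth muscle (0.0335) and epididymal genes (0.0273) were lower, with adjusted p = 0.403, 0.49 and 0.569 with an estimated correlation. In obese against lean fat the epididymal list was higher with 1 of 10 genes called (0.0138, and adjusted p = 0.569 with an estimated correlation). The summed level of the adipokine and fat expansion list went the other way from camera in both weight loss comparisons. It was 18076 CPM in lean fat, 14671 CPM in obese fat and 16135 CPM after weight loss.

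In obese against lean fat the lists of triglyceride synthesis, lipolysis, fatty acid oxidation, thermogenic adipocytes, cholesterol synthesis, T and NK cells, B cells, neutrophils, mast cells, endothelium, smooth muscle, mesothelium, testis, ovary, skeletal muscle, erythroid cells, sex-linked genes, endoplasmic reticulum stress, hypoxia and glucocorticoid response did not pass camera, with adjusted p from 0.0671 to 0.932. The sign of the median differed from that of camera for thermogenic, neutrophil, testis, skeletal muscle, endothelial, hypoxia and glucocorticoid genes. In weight loss against obese fat this held for oxidative phosphorylation, thermogenic, lipid-associated macrophage and glucocorticoid genes, and in weight loss against lean fat for lipolysis, inflammatory, endothelial, testis, cell cycle and glucocorticoid genes.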
